A study of Homo sapiens with 6 samples.

How the data were processed

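The series held RNA sequencing of 6 primary keratinocyte cultures from head and neck squamous cell carcinomas, with 1 library per culture, a sub-confluent state in every title and the same replicate number, 2, in each. The site label gave each culture its group: tongue, hard palate and alveolar ridge formed the oral cavity group, and skin, larynx and oropharynx the other group. The titles' shared number pairs nothing, so no block was fitted.

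For each library the authors deposited normalized gene counts, a signal that is never negative, with a gene identifier, symbol and type for each of 62696 genes. For 5 libraries the submitters' processing notes name cutadapt 4.6, FastQC 0.12.1, MultiQC 1.19, STAR 2.7.11b, Salmon 1.10.1, DESeq2 and the build GRCh38.p13, with no role or order, and the labels describe extraction with RNA STAT-60 and chloroform. For the tongue library the submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.7.10a and featureCounts 2.0.3, and its extraction label describes tissue of another organism and poly(A) enrichment. How counts were normalized, and whether counting used strand, was not given in the sources used here, so overlapping genes, antisense genes and close paralogs are uncertain.

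The scale of the values was examined in the files. In each library the value above 0 shared by the most genes was taken as the value of 1 read. The geometric mean of the 6 values was 1.00, and the median ratio of each library to the geometric mean over genes was 1.02 in all 6, so the libraries had been scaled together. Approximate depth was the total divided by this value, and was lowest in the oropharynx library. Only 2.71% to 6.90% of values below 200 were whole numbers of reads within a tolerance of 0.001, so whole reads were not recovered and tests on counts were not run. Why most values were not whole was not determined. The floor was set at 3 reads, 2.31 to 4.70 normalized counts, and covers counting error only.

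Values were analysed as log2(normalized count + 1), so a difference understates the change of low genes, and genes with a mean of at least 10 over the 6 cultures were kept (23863). Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Oral cavity and other cultures were compared with limma (a mean-variance trend, empirical Bayes moderation, all 6 libraries, no covariate) with Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. The level of a list was the mean over its measured members. Relations between lists were tested with exact permutation of the pairings, two-sided. A culture was said to stand apart when its gap to the nearest other, divided by the range of the 6, exceeded Dixon's critical value of 0.625. The tests were checked on simulated data with planted differences over 23863 genes. At the moderated SDs of the fit, 44 of 50 differences of log2 6 were recovered, with 4 false calls. In a separate simulation, 200 of 200 planted genes that set a culture apart were found. There the planted shift was far larger than the spread and larger than the gap asked for. Recovery could hardly fail, so this checks only that the rule was applied as stated.

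The 26 gene lists, of 462 symbols, were fixed before the data were examined, as were the groups, the tests and all alternatives not named below as added. They cover keratinocyte identity, simple epithelium, squamous differentiation, epithelial adhesion, mesenchymal transition, proliferation, senescence regulators, secreted senescence factors, p53 targets, citrate, prostaglandin, interferon, hypoxia, NRF2, head and neck cancer drivers, Notch, TGF-beta, positional factors, markers of fibroblasts, leukocytes, endothelium, melanocytes and muscle, mitochondrial mRNAs, histones and small non-coding RNAs. Of the symbols 1 matched no gene. Some genes belong to several lists.

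Named genes followed a rule set in advance: any list member with its level per culture; the 10 per direction with the largest limma statistic, since under 10 genes passed; the 20 genes with the largest SD; and, per culture, the 4 with the largest gap above and the 2 with the largest gap below the others. Genes linked to sex, genes with common germline deletions, HLA and immune receptor genes, pseudogenes and genes with no symbol were left out of naming. After the values were seen, pseudoautosomal genes and pseudogene copies of small RNAs were also left out, which brought the number left out to 6375 tested genes. Kallikrein and mucin genes were chosen after their values were seen. Coordinates are from GENCODE release 29 on GRCh38.

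The alternatives were pseudocounts of 0.5 and 8, no filter or a mean of at least 100, rescaling to the same total, by median of ratios or by quantiles, leaving out mitochondrial, histone and small non-coding genes, leaving out each culture in turn, limma without trend, with robust variances or with array weights, a range over 2 in place of the SD, and gaps of 2-fold and 8-fold. Leaving out the tongue and oropharynx cultures together was added after the data were seen, because of the conflicting label and the shallow library. Rescaling to the same total shifted the median gene by -0.19 (hard palate) to 0.35 (alveolar ridge) on the log2 scale, and quantile normalization by -0.10 to 0.06.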

Results

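RNA was sequenced from 6 primary cultures of keratinocytes, each grown from a head and neck squamous cell carcinoma and harvested below confluence. Each culture gave 1 library and is named here by the site of its tumour. The 3 oral cavity cultures came from the tongue, the hard palate and the alveolar ridge. The other 3 came from the skin, the larynx and the oropharynx. The division into oral cavity and other sites was made here from the site labels, which name no treatment. With 1 library per culture there was no replicate within a culture, so each SD is the spread between cultures from different tumours, and a single value has no replicate check. The extraction label of the tongue culture described heart tissue of another species and selection of polyadenylated RNA, which its keratinocyte and human labels contradict. RN7SL2, a non-polyadenylated RNA of the signal recognition particle, was nonetheless its most abundant gene, with 2.37% of its normalized counts, as in 4 of the other libraries, where it took 1.98% to 4.57%. The small non-coding list stood at 15.51 (log2) in it, inside the range of 14.84 to 15.98 in the others. RNU4-1, a small nuclear RNA, was in contrast at 7.69 in the tongue culture against 10.49 or more elsewhere. The submitters' processing notes of this library also differed from those of the other 5. Its values were on the same scale, with 6.42% of low values a whole number of reads within 0.001 reads, inside the range of 2.71% to 6.90% over all 6, and whether it was made or processed apart was not determined.

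The deposited normalized counts summed to 50323530 in the alveolar ridge library and to between 61004824 and 73088594 in the other 5. From the value that 1 read takes among low genes, depth was about 43.9 M reads in the oropharynx library and between 65.5 M and 72.1 M in the others. A value of 3 reads, taken as the floor, lay between 2.31 normalized counts in the alveolar ridge library and 4.70 in the oropharynx library, and covers counting error only. Of 62696 genes, between 29914 in the oropharynx and 34811 in the alveolar ridge library lay above 0, and 23863 with a mean of at least 10 were tested. Protein-coding genes took 84.6% to 89.7% of the normalized counts. Long non-coding RNAs took 7.35% in the oropharynx library and 2.80% to 4.30% in the others. The 2 mitochondrial ribosomal RNAs took 2.59% in the oropharynx library and at most 0.0479% elsewhere. Across the tested genes the log2 values of the 15 pairs of cultures correlated with Pearson's r between 0.829 and 0.882, where genes are not independent replicates. The tongue and skin cultures were the closest pair, with 7782 genes differing by over 2-fold, and the hard palate and alveolar ridge cultures differed in the most genes, 10398, while the hard palate and oropharynx cultures had the lowest r.

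The basal keratinocyte program was abundant in all 6 cultures and lowest in the alveolar ridge culture. KRT5, a keratin of basal keratinocytes (chromosome 12, 52514575 to 52520687), reached between 540857 and 907654 normalized counts in the tongue, hard palate, skin and larynx cultures, 135122 in the oropharynx culture and 107053 in the alveolar ridge culture. Its partner KRT14 (chromosome 17, 41582279 to 41586921) was at 3954 in the alveolar ridge culture and between 173033 and 739685 in the others. TP63, the transcription factor of stratified epithelium, was at 8098 in the alveolar ridge culture against 17433 to 36705 elsewhere. The mean level of the 20 keratinocyte and squamous identity genes was 16.00 ± 0.96 (log2, SD, n = 6 cultures), with 14.19 in the alveolar ridge culture and 15.94 to 16.86 in the others. The alveolar ridge culture had the lowest value for 15 of the 20 members, and 15 had an SD over 1. ITGB4, a hemidesmosome integrin gene, varied least, with an SD of 0.66.

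Keratins and surface proteins of simple epithelium differed more. KRT7, a keratin of simple and glandular epithelium, reached 63761 normalized counts in the oropharynx culture and 32083 in the alveolar ridge culture but at most 110 in the other 4. KRT19 was at 6.1 in the larynx culture against 7490 in the skin culture and 139782 in the tongue culture. ELF3, an epithelial transcription factor, ranged from 97 in the larynx to 19329 in the oropharynx culture. The 11 simple epithelial genes had a mean level of 12.40 ± 1.50 (log2, SD, n = 6), highest in the oropharynx culture (14.59) and lowest in the larynx culture (10.15), and 9 of the 11 had an SD over 1.

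Genes of suprabasal and terminal squamous differentiation varied most of the 26 lists. All 23 measured members had an SD over 1, and the list level was 9.99 ± 2.77 (log2, SD, n = 6). It was 13.29 in the tongue, 12.46 in the skin, 11.26 in the hard palate, 8.75 in the oropharynx, 8.01 in the larynx and 6.19 in the alveolar ridge culture. The mucosal keratins KRT4 and KRT13 were at 81925 and 78756 in the tongue culture and at 62 and 93 in the alveolar ridge culture. SPRR3, a cornified envelope precursor of mucosa, was at 45620 in the tongue culture and listed at 0 in the alveolar ridge culture. TGM3, CRNN and MAL, further genes of differentiated mucosa, were at 10835, 4833 and 8207 in the tongue culture and at most 166 in every other. The skin culture instead had the highest values of KRT1, DSG1 and KRTDAP, which belong to cornifying epidermis, at 17208, 57077 and 15755. The alveolar ridge culture was lowest for 13 of the 23 members.

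**Figure D1:**
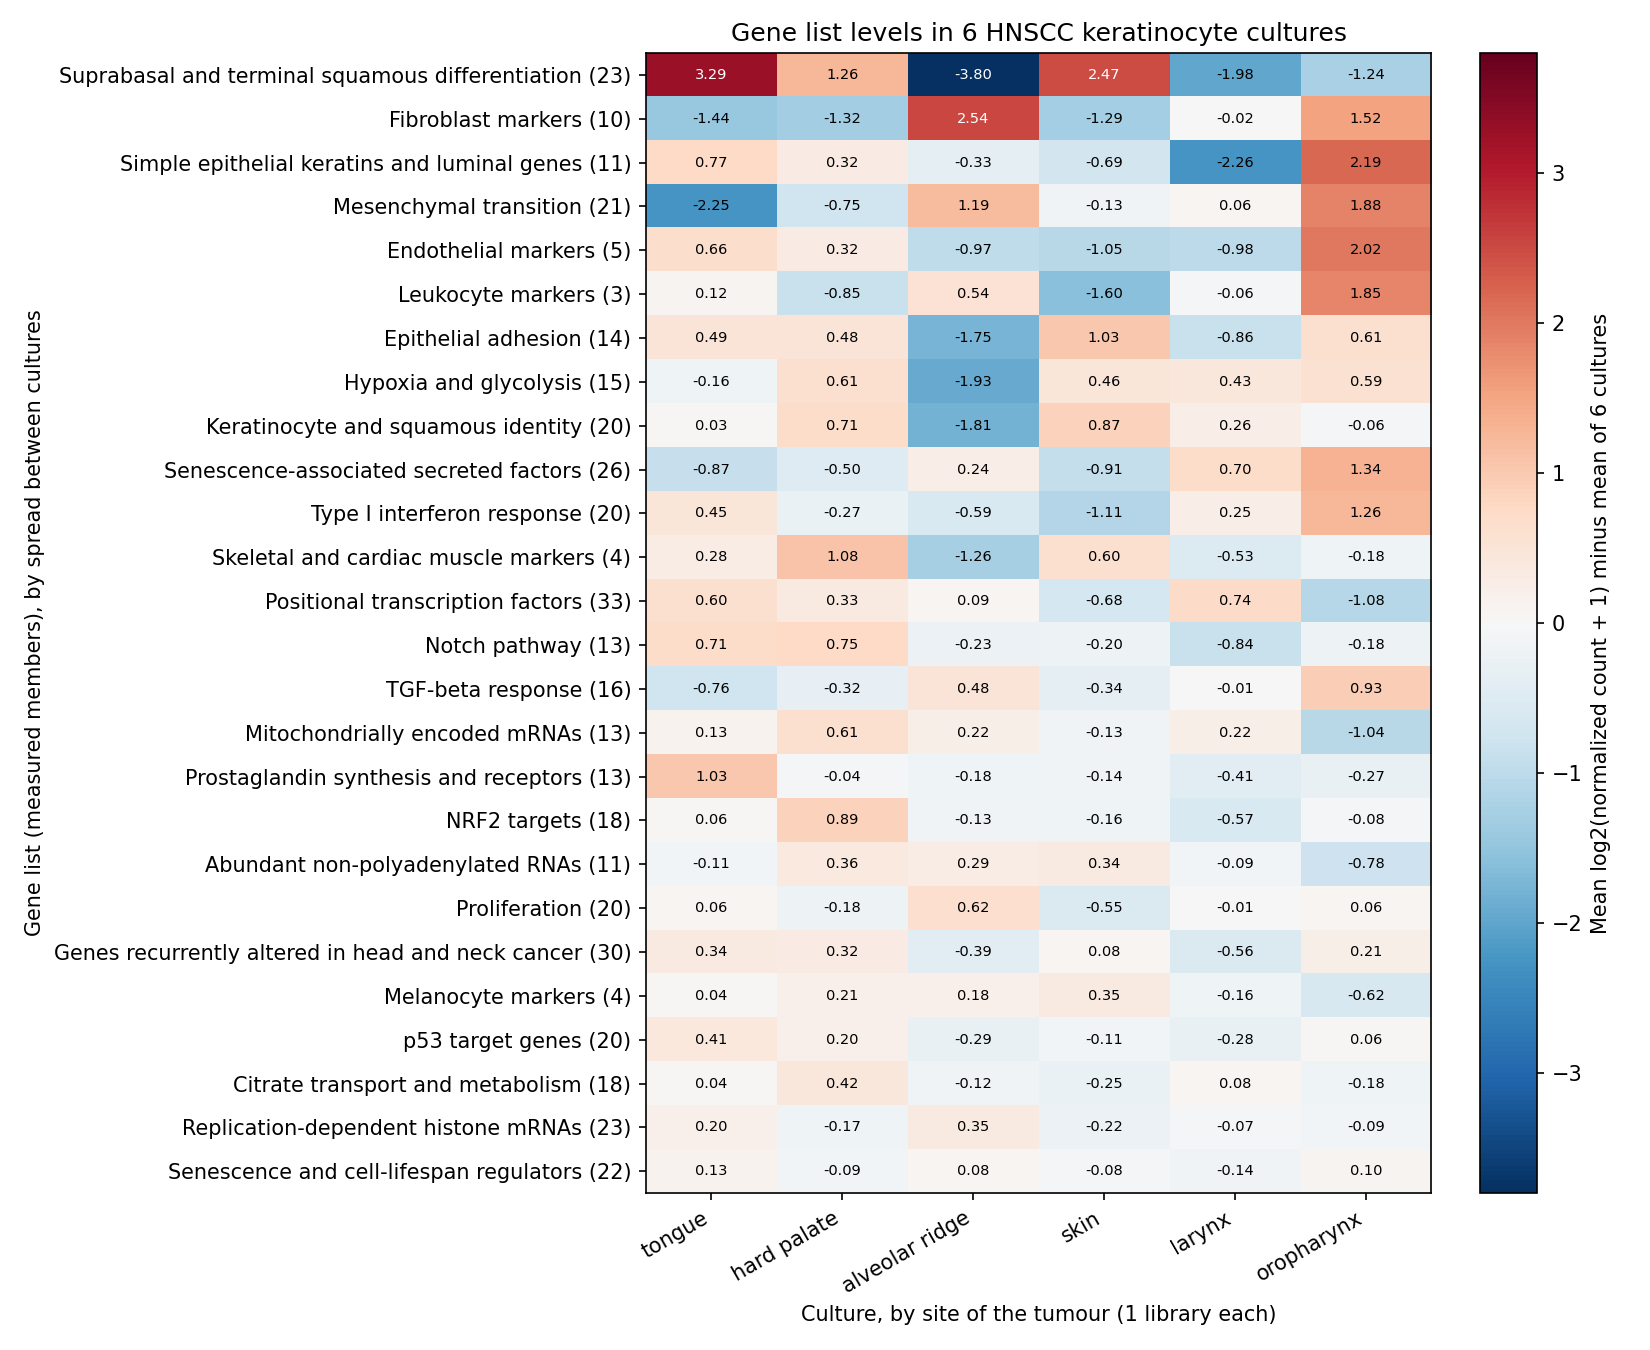
Heat map of the level of 26 gene lists in each of the 6 cultures (1 library each), as mean log2(normalized count + 1) of the measured members minus the mean over the 6 cultures. Lists are ordered by their SD between cultures, from 2.77 for squamous differentiation at the top to 0.12 for senescence regulators at the bottom.

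Epithelial adhesion genes were lowest in the alveolar ridge and larynx cultures. CDH1, which encodes E-cadherin, was at 6185 normalized counts in the alveolar ridge culture and between 17333 and 44837 in the others. ESRP1 and GRHL2, regulators of the epithelial state, were at 1851 and 472 in the alveolar ridge culture against 14514 to 26019 and 3060 to 7539 elsewhere. TJP1, a tight junction scaffold, hardly varied, with 10470 to 20615 normalized counts and an SD of 0.34. The 14 adhesion genes had a level of 12.62 ± 1.07 (log2, SD, n = 6), with 10.87 in the alveolar ridge, 11.76 in the larynx and 13.10 to 13.65 in the other cultures, and 11 of the 14 were lowest in the alveolar ridge culture.

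Mesenchymal genes were highest in the oropharynx and alveolar ridge cultures and lowest in the tongue culture, but different members led in each. FN1, which encodes fibronectin, reached 1071367 normalized counts in the oropharynx culture and 163333 in the alveolar ridge culture, against 224 in the hard palate culture. VIM, the mesenchymal intermediate filament gene, was listed at 0 in the tongue culture, at 437 in the skin culture and at 39607 in the larynx culture. TNC, CDH2 and ZEB1, encoding tenascin C, N-cadherin and a transcriptional repressor of E-cadherin, were highest in the alveolar ridge culture at 111181, 3687 and 781. INHBA and MMP10 were highest in the oropharynx culture, at 62398 and 10303. SNAI2, in contrast, ranged only from 4061 to 15959. The 21 mesenchymal transition genes measured had a level of 10.21 ± 1.46 (log2, SD, n = 6), from 7.96 in the tongue to 12.09 in the oropharynx culture, and 12 of the 21 were lowest in the tongue culture. The 16 genes of the TGF-beta response, which shares members with it, stood at 11.76 ± 0.61, with 12.69 in the oropharynx and 12.24 in the alveolar ridge culture, and were lowest in the tongue culture. PMEPA1, a TGF-beta target, was at 9847 in the alveolar ridge culture and 397 in the tongue culture.

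Fibroblast markers were highest in the same pair of cultures as the mesenchymal genes. The 10 of 12 that were measured had a level of 5.90 ± 1.69 (log2, SD, n = 6), highest in the alveolar ridge (8.44) and oropharynx (7.43) cultures and at most 5.88 elsewhere. COL5A1, a fibrillar collagen gene that carcinoma cells can also express, was at 22367 in the alveolar ridge culture. POSTN was at 1258 there and at most 18 in the others. COL1A2, an abundant transcript of fibroblasts, was at 14 in the alveolar ridge culture and 146 in the oropharynx culture.

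**Figure D2:**
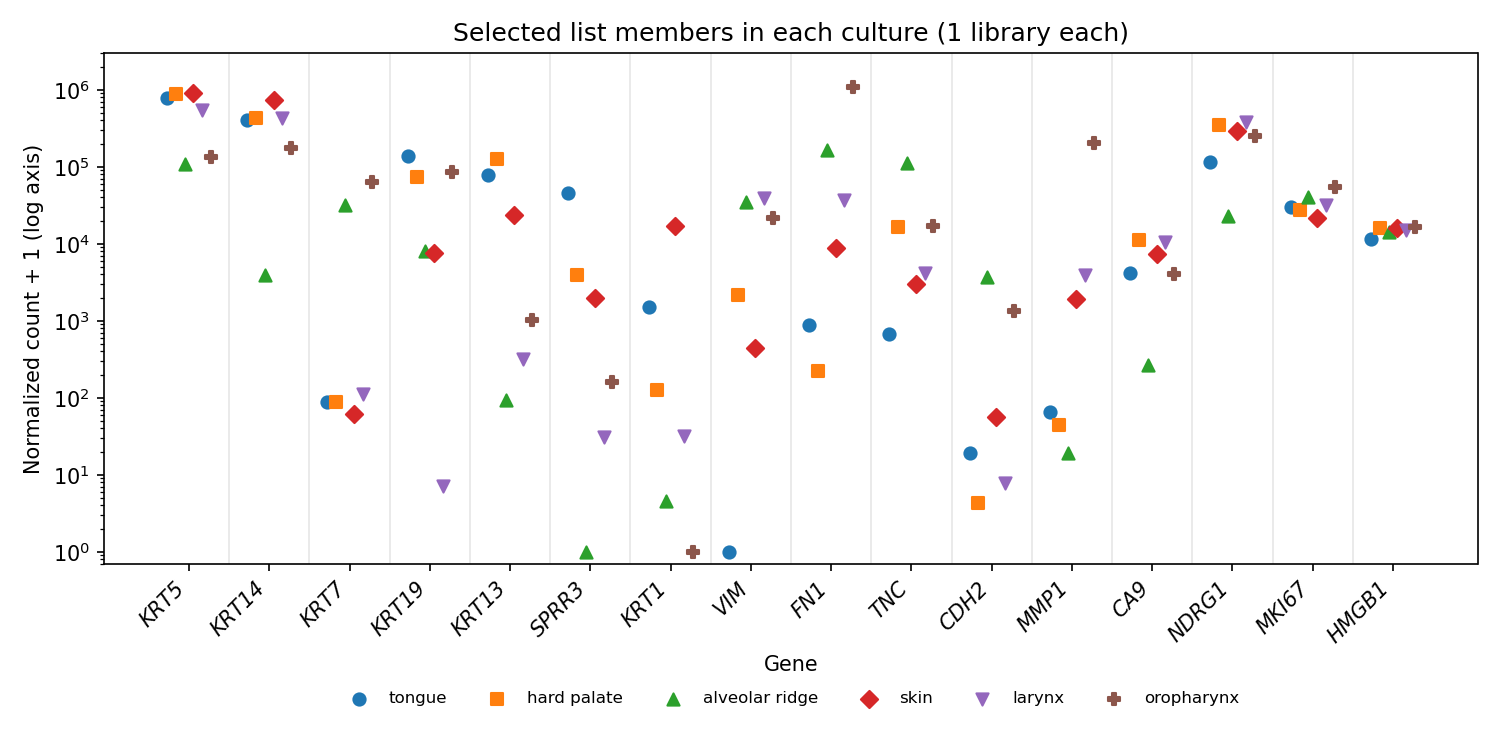
Normalized count plus 1 of 16 list members on a log axis, with 1 symbol per culture (1 library each). KRT14 stands at 3954 normalized counts in the alveolar ridge culture and at 173033 or more in the others, while HMGB1 lies between 11585 and 16505 in all 6.

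Proliferation and senescence lists had similar mean levels in the cultures. MKI67, the proliferation marker, lay between 21417 and 53997 normalized counts, and TOP2A, a topoisomerase of dividing cells, between 26763 and 48823. The 20 proliferation genes had a level of 12.45 ± 0.38 (log2, SD, n = 6), from 11.89 in the skin to 13.07 in the alveolar ridge culture, and 3 of the 20 had an SD over 1. E2F1, a transcription factor of S phase entry, was at 4971 in the alveolar ridge culture and at most 1257 in the others. The 22 regulators of senescence and cell lifespan had the steadiest mean level of all lists, 11.99 ± 0.12, but their members went both ways, with a median member SD of 0.65 against 0.44 for the histones. Among them HMGB1, a chromatin protein, had an SD of 0.19. CDKN2A, which encodes p16, ranged from 1267 in the larynx to 11793 in the alveolar ridge culture, and TERT, the telomerase catalytic subunit, from 15 in the hard palate to 162 in the oropharynx culture. The 20 p53 target genes stood at 10.39 ± 0.28, with MDM2 between 7850 and 17591 and CDKN1A between 7834 and 29441.

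Secreted factors of the senescence-associated secretory phenotype varied widely, with 22 of 26 measured members at an SD over 1. MMP1, an interstitial collagenase, was at 205662 normalized counts in the oropharynx culture and at 18 in the alveolar ridge culture. IGFBP3 was at 182979 in the tongue culture and 459 in the larynx culture. IL6 was below the floor of 3 reads in the tongue and hard palate cultures and at 447 in the alveolar ridge culture. The list level was 10.10 ± 0.91 (log2, SD, n = 6), from 9.19 in the skin to 11.43 in the oropharynx culture. Of 13 genes of prostaglandin synthesis and response, PTGS1 and PTGS2, the cyclooxygenases, were highest in different cultures, PTGS1 in the hard palate culture at 42687 and PTGS2 in the larynx culture at 9231. HPGD, which degrades prostaglandins, was at 1576 in the tongue culture and at most 79 in the others. The prostaglandin list stood at 9.67 in the tongue culture and at 8.23 to 8.60 in the others (8.64 ± 0.52, log2, SD, n = 6).

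Hypoxia and glycolysis genes were lowest in the alveolar ridge culture for 14 of 15 members. CA9, a carbonic anhydrase induced by hypoxia, was at 269 normalized counts there and between 4002 and 11107 in the others. NDRG1, another hypoxia-induced gene, was at 22692 against 115445 to 380242, and SLC2A1, the glucose transporter GLUT1, at 7550 against 19391 to 104846. ENO1, a glycolytic enzyme, varied least, with an SD of 0.34. The list level was 14.29 ± 0.99 (log2, SD, n = 6), with 12.36 in the alveolar ridge culture and 14.13 to 14.90 in the others. The 18 measured genes of citrate transport and metabolism, in contrast, stood at 11.68 ± 0.24, and none had an SD over 1. Of these, FASN, fatty acid synthase, ranged from 19737 in the alveolar ridge to 69136 in the tongue culture, and ANKH, a membrane transporter of pyrophosphate and citrate, was at 1460 in the skin culture and 4358 to 6462 in the others.

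The 18 targets of the oxidative stress regulator NRF2 stood at 11.13 ± 0.48 (log2, SD, n = 6), highest in the hard palate culture at 12.02. AKR1B10, an aldo-keto reductase, was at 12001 there and at 37 in the alveolar ridge culture. NQO1, a quinone reductase, was at 870 in the larynx culture and 3115 to 11697 in the others. The 20 genes of the type I interferon response stood at 10.51 ± 0.84, from 9.41 in the skin to 11.78 in the oropharynx culture. MX1, an antiviral GTPase, was at 383 in the skin and 8324 in the oropharynx culture. IFI27 was at 251 in the alveolar ridge culture against 5458 to 7770 elsewhere.

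Of 30 genes recurrently altered in head and neck cancer, 20 had an SD of at most 1, and their level was 12.45 ± 0.38 (log2, SD, n = 6). EGFR, the epidermal growth factor receptor, lay between 49192 and 121354 normalized counts in all 6. NOTCH3 was at 53 in the larynx culture and 4311 to 32362 in the others, and NOTCH1 was at 37388 in the tongue culture and 2697 in the hard palate culture. The 13 Notch pathway genes stood at 10.75 ± 0.62, from 9.91 in the larynx to 11.51 in the hard palate culture. Of 33 measured positional transcription factors, which carry positional identity in development, 25 had an SD over 1, at a level of 7.31 ± 0.73. PITX1 and PAX9, factors of jaw and oral epithelium, were highest in the tongue culture at 18583 and 11051, while PAX9 was at 11 in the oropharynx culture. HOXA9 was at 2501 in the larynx culture and at most 88 in the others, and HOXB7 was listed at 0 in the tongue culture and at 142 to 897 elsewhere.

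Markers of leukocytes and muscle were mostly unmeasured, and those of endothelium and melanocytes were measured in part. Of 13 leukocyte markers 3 reached a mean of 10, at a mean level of 8.90 (log2, n = 6), led by CD68, a lysosomal gene that epithelial cells also express, at 12853 normalized counts in the oropharynx culture. Of 9 endothelial markers 5 were measured, at 5.30 ± 1.23, with TEK at 324 in the oropharynx culture and at most 12 in the others. Of 7 melanocyte markers 4 were measured, at 6.80 ± 0.35, and MITF lay between 186 and 770. Of 11 markers of skeletal and cardiac muscle 4 were measured, at 5.98 ± 0.83, and TTN was at 74 in the tongue culture against 774 to 2558 in the others.

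All 13 mRNAs encoded by mitochondrial DNA were lowest in the oropharynx culture. MT-CO1, a cytochrome oxidase subunit, was at 203015 normalized counts there and between 520216 and 644653 in the others, and the list stood at 14.78 against 15.69 to 16.44 (15.82 ± 0.56, log2, SD, n = 6). This was also the shallowest library and the one with the highest share of mitochondrial ribosomal RNA. Of 11 abundant RNAs without a poly(A) tail 8 were lowest there, and SCARNA2 was at 2445 against 4963 to 5533 (list level 15.62 ± 0.44). The 23 replication-dependent histone mRNAs stood at 12.17 ± 0.23, and H1-4 lay between 10352 and 12505 in all 6. H4C1 was at 38 in the larynx culture and 1594 to 1876 in the others.

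Of the 23863 tested genes, 8057 (33.8%) had an SD over 1 between the cultures on the log2 scale, and the median SD was 0.71. Such genes made up 31.7% of 15382 protein-coding genes and 40.7% of 5889 long non-coding RNAs, but among genes with a mean of 100 to 1000 the order was the opposite, 43.5% against 30.6%. The 20 most variable genes included the epidermal genes CASP14 and LGALS7 as well as SPRR3, KRT1, KRT19 and VIM. CASP14, a caspase of cornifying keratinocytes, was at 35212 in the skin culture and at 2.5 in the tongue culture. GDA, guanine deaminase, was at 28595 in the tongue culture and at most 615 elsewhere. SFRP1, a secreted Wnt antagonist, was at 14925 in the oropharynx culture, 28 in the tongue culture and listed at 0 in the hard palate culture. IGFBP2 was at 22344 in the hard palate culture and listed at 0 in the oropharynx culture, LDOC1 was at 2169 and 2551 in the hard palate and skin cultures and at most 0.8 in the others, and TFPI2, WDR72, GALNT5 and EPIC1 had SDs of 5.59, 5.29, 5.59 and 5.40. UPK3BL2, LGALS7, H4C6 and ZNF320 have close paralogs, so their values are uncertain.

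Genes that set a single culture apart were counted where its value lay at least 4-fold above the highest, or below the lowest, of the other 5. There were 1307 above and 1840 below. The oropharynx culture had 317 above and 431 below, led by the imprinted non-coding RNAs MEG3 (4364 normalized counts against at most 11) and MEG8 (3095 against at most 8.7) and by SRGN, a proteoglycan gene of secretory granules (4837 against at most 35). The alveolar ridge culture had 214 above and 409 below. In it the cyclin gene CCND2 was at 8.8 against 5812 to 48891, CERS3, a ceramide synthase of the epidermal barrier, at 0.9 against 384 to 5979, and AMPH at 1094 against at most 0.8. The larynx culture, with 141 above and 312 below, had PRDM9, a meiotic histone methyltransferase, at 1457 against at most 1.6 and the transcription factor gene ZIC1 at 414 against 0 in the others. The hard palate culture, with 284 above and 282 below, had BRINP1 at 1036 against at most 0.8 and GOLGA4, a Golgi protein gene, listed at 0 against 5668 to 9212. OXSR1 was also listed at 0 in it, against 5382 to 7999. Both lie on chromosome 3, GOLGA4 at 37243177 to 37366751 and OXSR1 at 38165089 to 38255488. The tongue culture had 256 above and 165 below, with CEACAM7 at 1064 against at most 1.1 and PCDH19, a protocadherin, at 1485 against at most 4.4. The skin culture had 95 above and 241 below, with SVIP at 912 against at most 0.7 and MAP9 at 321 against at most 1.4. These counts come from a rule of size and not from a test. A listed 0 is the normalized count given. No reads and no DNA were examined, so a 0 does not by itself mean low expression. It was not told apart from a gene whose reads were not counted.

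**Figure D3:**
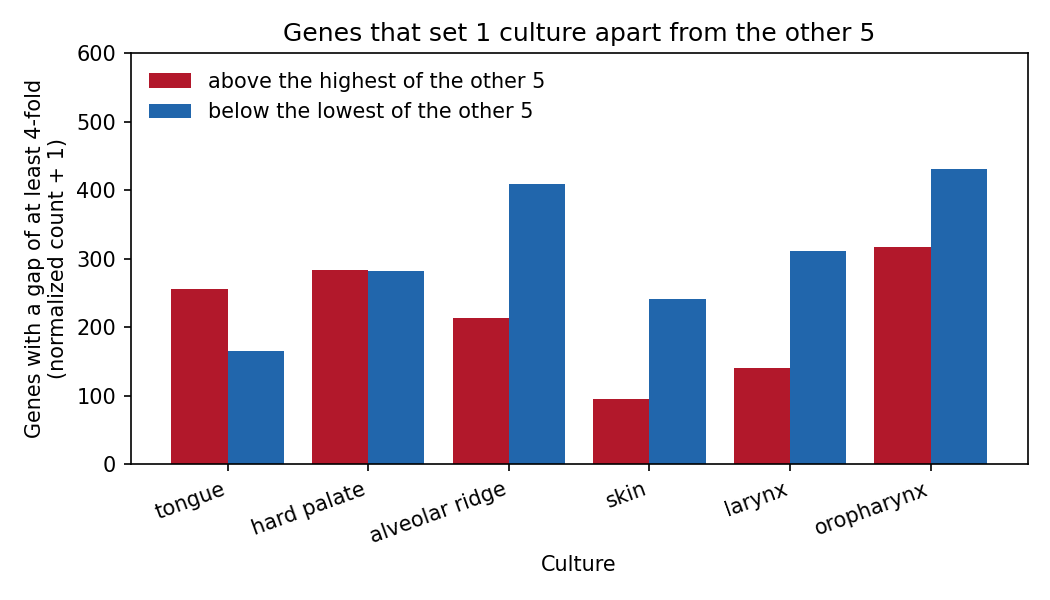
Bars give the number of genes in each culture (1 library each) at least 4-fold above the highest or below the lowest of the other 5, on the normalized count plus 1. The counts run from 95 above in the skin culture to 431 below in the oropharynx culture.

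The comparison of the 3 oral cavity cultures with the other 3 asked whether the site of the tumour was reflected in the expression of its keratinocytes. The genes named here ranked highest by the test, and none of them passed its threshold. RPP25, a subunit of ribonuclease P and MRP, was at 1278, 1232 and 1392 normalized counts in the tongue, hard palate and alveolar ridge cultures against 49.6, 60.9 and 66.1 in the skin, larynx and oropharynx cultures, a log2 difference of 4.45 with an SE of 0.37. ZNF568, a zinc finger gene with close paralogs, was at 203 to 997 in the oral cavity cultures and listed at 0 in the other 3. WNK3, a kinase of ion transport, was at 558 to 1077 against 13.7 to 38.9, and the receptor gene LRP3 at 700 to 1084 against at most 8.9. TMEM200A was at 1.5 to 7.7 in the oral cavity cultures against 239 to 813, a log2 difference of -6.63 with an SE of 0.76. TRAF3IP3, an adaptor of immune signalling, was at 254 to 542 against 3257 to 6905, HEPHL1, a ferroxidase, at 404 to 1634 against 7486 to 28951, and MAN1A1, a mannosidase of N-glycan processing, at 9.2 to 83.8 against 543 to 2422.

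In limma with a mean-variance trend, 0 of the 23863 genes passed an adjusted p of 0.05, and 1009 had an unadjusted p under 0.05. The smallest adjusted p was 0.101, for RPP25 and ZNF568, both higher in 3 of 3 oral cavity cultures than in any other. The other genes named by rank, higher in the oral cavity (MAGED4B, ZNF354C, RIPPLY2, PWAR5, MTARC1 and SYNGR3) or lower (CCDC8, LNCAROD, C1orf74, SLC35F3, EPIC1 and ALPK2), had adjusted p values up to 0.515. limma without the trend, with robust variances and with array weights also called 0 genes, with 1002, 1004 and 1192 at an unadjusted p under 0.05. Without the alveolar ridge culture 1 gene passed, the long non-coding RNA EPIC1, listed at 0 in the tongue and hard palate cultures against at least 1765 in the 3 other cultures (adjusted p = 0.0275). The 3 oral cavity cultures all lay above, or all below, the other 3 for 2129 genes (8.92%), against 10% by chance. Without the tongue culture 0 genes passed and 942 had an unadjusted p under 0.05. Data were also simulated with the moderated SDs of the fit. At planted log2 differences of 1, 2, 4 and 6 in turn, 0, 4, 19 and 44 of 50 genes were recovered. Moderated SDs vary less between genes than unmoderated ones. The planted differences of all sizes, 50 genes each, were also adjusted together, and many true differences make the adjusted threshold easier to pass. For both reasons this recovery need not hold for the real data. ZNF568, for example, differed by 9.02 and did not pass.

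Of the gene lists, 6 passed an adjusted p of 0.05 in camera with a preset correlation of 0.01. Of the 10 splits of the cultures into 3 and 3, this one included, 8 gave at least 6 lists. The mitochondrially encoded mRNAs were higher in the oral cavity cultures for 13 of 13 members, by a mean log2 difference of 0.64 (adjusted p = 2.9e-05), and the oropharynx culture had the lowest value of each. Hypoxia and glycolysis genes were lower for 13 of 15 members, by -0.99 (adjusted p = 1.4e-04), keratinocyte identity genes for 18 of 20, by -0.71 (adjusted p = 0.0112), and adhesion genes for 11 of 14, by -0.52 (adjusted p = 0.0422). In each of these 3 lists the alveolar ridge culture held the lowest level. NRF2 targets were higher for 16 of 18 members, by 0.54, and positional transcription factors for 23 of 33, by 0.68, both with an adjusted p of 0.0150. PITX1 was at 5506 to 18583 in the oral cavity cultures against 2285 to 2721, and SIX2, a homeobox gene, at 467 to 1240 against 3.2 to 205. No list held with an estimated correlation: all 6 had an adjusted p = 0.728 with an estimated correlation, and fry, which tests whether the genes of a list move in a single direction on balance, gave adjusted p values of 0.792 to 0.998 over the 26 lists.

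The calls of all 6 lists depended on single cultures, and those of 3 also on the processing. In camera the keratinocyte (-0.49) and adhesion genes (-0.45) both had an adjusted p of 0.0800 after quantile normalization, the adhesion genes 0.0508 at a mean of at least 100, and the positional factors 0.0586 with no filter. The difference was unchanged at -0.52 for the adhesion genes at that mean, so there only the p crossed 0.05. For the positional factors it went from 0.68 with 33 members to 0.61 with 35. Without the oropharynx culture the mitochondrial mRNAs had an adjusted p of 0.0591 in camera, the positional factors 0.409 and the adhesion genes 0.216. Without the alveolar ridge culture the hypoxia genes had 0.235, and the keratinocyte and adhesion genes both 0.892, with differences of 0.02 and 0.23 in the opposite direction. Without the skin culture the keratinocyte and adhesion genes had 0.100 and 0.398, with differences of -0.46 and -0.14 (main -0.71 and -0.52). Without the tongue culture the positional factors had 0.0724, with a difference of 0.55 (main 0.68). The NRF2 targets had 0.309 without the hard palate and 0.109 without the larynx culture, with differences of 0.23 and 0.39 (main 0.54).

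The other 20 lists did not pass in the main setting, though 11 of them passed in at least 1 alternative. The lowest adjusted p among them in camera was 0.0519, for the small non-coding RNAs (0.36), followed by 0.0648 for the mesenchymal genes (-1.21). The remaining mean log2 differences between oral cavity and other cultures were 0.82 for the Notch pathway, -0.75 for the senescence-associated secreted factors, 0.55 for prostaglandin genes, -0.39 for the TGF-beta response, 0.33 for proliferation, -0.27 for the interferon response, 0.25 for histones, 0.23 for citrate genes, 0.22 for p53 targets and 0.08 for senescence regulators. Markers of melanocytes, fibroblasts, leukocytes, muscle and endothelium differed by 0.29, -0.15, -0.13, 0.07 and 0.01. Simple epithelial genes (0.51), squamous differentiation genes (0.50), driver genes (0.18) and the muscle and endothelial markers had a mean above 0 while camera ranked them down. Adjusted over the list alone, 1 member passed in each of 3 lists, picked out after its values were seen: MMP10 in the mesenchymal list (-6.34, adjusted p = 0.0354 by limma), MMP1 among the secreted factors (-8.25, 0.0468) and TERC, the telomerase RNA, among the small non-coding RNAs (1.68, 0.0374). In the other 23 lists 0 members passed when adjusted over the list alone, and 0 members of any list passed over all genes tested.

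The 11 lists that passed only in an alternative depended on which cultures were compared, and on the preset correlation. With an estimated correlation all 26 lists had adjusted p values of 0.728 to 0.999 in camera over the 6 cultures, and it was not estimated with cultures left out. With all cultures and the preset correlation, the small non-coding RNAs, higher in the oral cavity, passed with a pseudocount of 0.5 (adjusted p = 0.0488 in camera), the same total (0.0211), the median of ratios (0.0488) and quantile normalization (0.00240). The mesenchymal genes, lower, passed with no filter (0.0403) and the same total (0.0197), the secreted factors, also lower, with the same total (0.0432), and proliferation (0.0156) and histones (0.0217), both higher, with quantile normalization. With 1 culture left out, camera called the interferon response lower (0.0270) and small non-coding RNAs higher (0.0275) without the tongue culture, and proliferation (0.0119) and histones (0.00954) higher without the hard palate culture. Without the skin culture it called the interferon response (9.77e-05), secreted factors (0.000340), mesenchymal genes (0.0154) and the TGF-beta response (0.0347) lower, and small non-coding RNAs (0.000938) and squamous differentiation (0.0257) higher. Without the alveolar ridge culture it called mesenchymal genes (0.000238), secreted factors (0.00480), the TGF-beta response (0.0118) and fibroblast markers (0.0246) lower, and squamous differentiation (0.00107) and the Notch pathway (0.00347) higher, and without the oropharynx culture proliferation (0.0346) and simple epithelial genes (0.0388) higher.

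Some of these calls changed sign or shrank with other cultures left out. Without both the tongue and oropharynx cultures, a setting chosen after the data were seen, camera called squamous differentiation lower (-1.51, adjusted p = 0.0137) and fibroblast markers higher (1.26, 0.0425), against 2.53 and -1.45 without the alveolar ridge culture, and also called proliferation (0.50, 0.0149) and simple epithelial genes (1.47, 0.0275) higher. Without the oropharynx culture alone the log2 difference was 0.06 for the small non-coding RNAs (adjusted p = 0.675 in camera), -0.57 for mesenchymal genes (0.409), -0.27 for secreted factors and -0.03 for the TGF-beta response. Without the tongue culture it was -0.38 for mesenchymal genes (0.916). The prostaglandin genes, which passed in no setting, differed by 0.17 without the tongue culture.

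Relations between gene lists were tested over the 6 cultures for 4 pairs fixed in advance, and none passed. The values of r with 2 cultures left out are for those farthest from the median of the first list, and other pairs were not left out. Keratinocyte identity and squamous differentiation genes, both lowest in the alveolar ridge culture, had Pearson's r of 0.721 (exact permutation p = 0.075, adjusted p = 0.3) and Spearman's rho of 0.54 (exact p = 0.297), but r was 0.104 without the alveolar ridge and skin cultures. Interferon response and secreted factors had r of 0.648 (exact p = 0.172, adjusted p = 0.344) and rho of 0.60 (exact p = 0.242), and r of -0.234 without the oropharynx and skin cultures. Proliferation and secreted factors had r of 0.440 (exact p = 0.414, adjusted p = 0.517) and rho of 0.37 (exact p = 0.497), and r of 0.358 without the alveolar ridge and skin cultures. Adhesion and mesenchymal genes had r of -0.334 (exact p = 0.517, adjusted p = 0.517) and rho of -0.14 (exact p = 0.803), and r of 0.275 without the alveolar ridge and larynx cultures. Without the tongue culture the 4 values of r, in the same order, were 0.874, 0.901, 0.539 and -0.256 over 5 cultures (exact p = 0.0333, 0.05, 0.367 and 0.65; adjusted p = 0.1, 0.1, 0.489 and 0.65). All tests were two-sided, and the smallest exact p that 6 cultures allow was 0.00278.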

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

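The tests of scaling, fibroblast content, mitochondrial ribosomal RNA, small non-coding RNAs and other splits of the cultures were chosen after their results were seen, and that of the nuclear respiratory chain genes was not.

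A gene list, library measure or gene was singled out when the highest or lowest culture lay far from the other 5, its gap exceeding the critical share of the range for 6 values. Chance gives about 1 in 20. This picked out 3 of 26 lists, 3 of 8 library measures, 18 of 173 named genes and 33 of 405 measured list members. Many of the named genes were chosen for their values, so their share cannot be set against chance. Genes named only because they set a culture apart were not looked at in this way.

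In the alveolar ridge culture the keratinocyte list (0.655 of the range) and the hypoxia list (0.699) lay below the others, as did KRT14 (0.722), ESRP1 (0.779), GRHL2 (0.674), ST14 (0.632), CA9 (0.725) and IFI27 (0.897). The gap was 1.77 on the log2 scale for the hypoxia list and 1.76 for the keratinocyte list. Scaling between libraries does not account for the hypoxia gap, which was 1.49 or more under 3 other scalings. The keratinocyte gap fell to 1.31 with the same total and 1.17 with quantile normalization, where that list no longer stood apart (0.581 and 0.580 of the range). Fibroblasts in place of keratinocytes would have to make up 70.4% of the RNA to give the keratinocyte gap of 1.76. Of 12 fibroblast markers 5 exceeded the median tested gene of that library (269.2), and COL1A2 was at 14. The level of the fibroblast list was nonetheless highest in this culture (8.44). A count of markers cannot exclude a smaller share of fibroblasts, which was not tested. A lower expression of both programs in these tumour cells stays open as a biological explanation. So do a smaller share of fibroblasts, the state of the culture at harvest and effects of a single library. With 1 library per culture these cannot be separated.

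In the oropharynx library the mitochondrial ribosomal RNA share (0.982), the long non-coding share (0.671) and TEK (0.8) stood above the others, and the approximate number of reads (0.766), MT-CO1 (0.814), MT-CO2 (0.647) and SCARNA2 (0.867) below them. Reads of mitochondrial ribosomal RNA taking depth from the other genes would lower them by 0.0379 on the log2 scale, far below the median difference of -1.26 of the 13 mitochondrial mRNAs. A difference in library preparation is a candidate explanation, as 8 of 11 small non-coding RNAs were also lowest there. A lower expression of the respiratory chain as a whole is another, as 33 nuclear-encoded genes of the chain had a median difference of -0.79 (interquartile range -0.99 to -0.33) and 23 of them were lowest in this culture. Both remain open.

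Single values also stood apart in the other cultures. In the tongue culture these were the prostaglandin list (0.743, higher, though only 1 of its 13 members, HPGD, was highest there), HOXB7 (0.729, lower), TTN (0.662, lower) and RNU4-1 (0.661, lower). In the larynx culture they were KRT19 (0.704, lower), NOTCH3 (0.685, lower), HOXA9 (0.714, higher) and H4C1 (0.958, lower). In the skin culture ANKH was lower (0.735).

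Between oral cavity and other cultures limma called 0 genes, so that all 10 of the 10 splits of the 6 cultures into 3 and 3 necessarily gave at least as many, and this count decides nothing. The highest of the others was 22 genes. For the lists camera called 6, 8 of the 10 splits gave at least as many, and the highest other gave 12. The number of lists called was thus no higher than for most other groupings of the same cultures, and does not mark out the oral cavity. The 10 splits are in any case too few for a share under 0.05.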

How the results depend on the processing

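The setting without the tongue and oropharynx cultures was chosen after the data were seen, and all other alternatives before. No paired analysis was possible because all titles carry the same replicate number and each culture has 1 library. Tests on counts were not run, as whole reads were not recovered, and differences under the floor of 3 reads, highest in the oropharynx library at 4.70, are not detectable. Of 4759 alternative values, 4607 were unchanged in kind (the same direction and side of the threshold for a test, a count within 1.5-fold, an SD changed by less than itself), 65 moved, 26 were weaker, 30 stronger and 31 reversed. An SD could in practice move only by rising by at least its own size. The 4607 thus include values that could hardly move, and do not measure how firm the called lists are. Genes past the threshold between oral cavity and other cultures numbered 0 to 1 when each culture was left out, the 1 without the alveolar ridge culture, and 0 in the other alternatives. The 6 lists became 0 with an estimated correlation and 0 with fry, and 5 to 10 when each culture was left out, with 10 without the skin culture. Of the 20 other lists 11 passed in at least 1 alternative, 5 of them in an alternative with all cultures. List levels standing apart numbered 3, and 2 with the same total, with quantile normalization and at a mean of at least 100, and 1 to 4 when each culture was left out. Relations between lists numbered 0 in each setting tried, and were not tested without the tongue and oropharynx cultures together. The 8057 variable genes became 14676 with no filter and 3728 at a mean of at least 100, with 42975 and 15105 genes entered. The 3147 genes that set a culture apart became 5131 and 1529 under these filters, 1901 with a pseudocount of 8, and 1389 and 9097 with gaps of 8-fold and 2-fold.

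The mean log2 differences of several lists reversed, and the cause was not tested. Without the tongue and oropharynx cultures they were -1.51 for squamous differentiation (main 0.50; adjusted p = 0.0137 in camera), 0.25 for mesenchymal genes (-1.21), 0.25 for the TGF-beta response (-0.39), 1.26 for fibroblast markers (-0.15; 0.0425), 0.67 for leukocyte markers (-0.13) and -0.13 for muscle markers (0.07). Endothelial markers (0.01) moved to -0.0575 with a pseudocount of 8, -0.11 with no filter and -0.15 with quantile normalization, which also moved muscle markers to -0.0884. Leaving out each culture in turn gave -1.24 to 0.0178 for keratinocyte identity, -0.49 to 1.73 for simple epithelial genes, -1.02 to 2.53 for squamous differentiation, -1.08 to 0.23 for adhesion, -0.90 to 0.29 for interferon, -0.0582 to 0.41 for drivers, and for markers of fibroblasts -1.45 to 0.58, leukocytes -0.96 to 0.76, endothelium -0.51 to 1.02 and muscle -0.46 to 0.71. By camera, squamous differentiation passed with a positive difference without the alveolar ridge (2.53, adjusted p = 0.00107) and skin cultures (1.86, 0.0257), each left out alone, fibroblast markers without the alveolar ridge culture (-1.45, 0.0246), interferon without the skin (-0.90, 9.77e-05) and tongue cultures (-0.57, 0.0270), and simple epithelial genes without the oropharynx culture (1.73, 0.0388).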

Other observations

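All tests in this part were chosen after the result was seen, as were the 2 gene families described.

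Kallikreins, serine proteases of which some shed cells from the epithelial surface, differed by orders of magnitude between the cultures. KLK10 was at 74291 normalized counts in the tongue culture and 85 in the alveolar ridge culture, KLK5 at 51384 and 14, and KLK13 at 13636 in the tongue culture and listed at 0 in the alveolar ridge culture. Of 11 kallikrein genes 8 were highest in the tongue culture and 8 lowest in the alveolar ridge culture. The 5 mucins shared no single highest culture, with 2 highest in the tongue, 2 in the oropharynx and 1 in the hard palate culture. MUC1, MUC4, MUC16 and MUC20 were each higher in the tongue and oropharynx cultures than in any other, and MUC21 was not. MUC16 was at 128861 in the tongue and 95844 in the oropharynx culture against 142 in the larynx culture, MUC4 at 26060 in the oropharynx culture against 10 in the skin culture, and MUC21 at 3428 in the hard palate culture against at most 52 in the others.

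The hypothesis that kallikreins vary with squamous differentiation was tested over the 6 cultures. The mean of 10 kallikreins and the level of the differentiation list, from which KLK7 was removed, had Pearson's r of 0.942. The kallikreins were chosen after their values were seen, and the tongue and alveolar ridge cultures are the extremes of both, so no p is given for the 6 cultures. Without the alveolar ridge and tongue cultures r was 0.824 (exact p = 0.125). The relation was left open.

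The hypothesis that squamous differentiation is lower where mesenchymal genes are higher gave Pearson's r of -0.776 (exact permutation p = 0.0694) and rho of -0.77 (exact p = 0.103), and r of -0.546 without the alveolar ridge and tongue cultures (exact p = 0.5). Of all 325 pairs of lists 17 had an r at least as negative. The tests leave this relation open at 6 cultures.

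Genes that set the same culture apart in the same direction lay next to each other more often than by chance. There were 256 adjacent pairs, against a mean of 28.7 and a highest value of 47 in 1000 random placements among 17287 genes. Without pairs that overlapped or had like symbols the count fell to 116, against a mean of 20.5 and a highest of 36. Such pairs thus made up part of the 256 but not the whole excess. The 116 ranged from 1 among the 115 genes lower in the tongue culture to 20 among the 285 lower in the oropharynx culture. Larger sets give more pairs by chance: for all adjacent pairs the random means of these sets were 0.76 and 4.68. Related genes with unlike symbols were not left out, so reads shared between relatives were not excluded. An influence shared by neighbouring genes may contribute; which kind was not tested.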
